A study of Rattus norvegicus with 3 samples.

How the data were processed

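Gene expression in rat kidney inner medulla was measured on 3 dual-colour spotted arrays, each setting RNA of rats treated with lithium for 1 month against RNA of control rats. Per the labels, lithium RNA was labelled red (channel 1) and control RNA green (channel 2) on every array, so no dye swap separates dye effects from treatment. Arrays 1 and 2 held RNA of 2 rats per channel and array 3 of 1 rat. The labels give the arrays different rats, so the spread between arrays includes that between animals or pools.

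The deposited values were log ratios with 2 decimals for 5760 probes, laid out in 32 blocks of 180 spots. The scanner, background correction, normalization, filter on dim spots and log base were not given in the sources used here. The deposited column medians were −0.02, −0.04 and 0.00, and whether the submitters centred the ratios, their scale and their direction stayed unknown. Reading them as lithium over control is likely because the labels put lithium in channel 1 and ratios are usually red over green. The values ran from −1.14 to 0.61, −1.56 to 0.55 and −0.60 to 0.70, and their SDs were 0.135, 0.198 and 0.115. Empty probes numbered 178, 78 and 1473 on arrays 1, 2 and 3, and 4250 probes had a value on all 3 arrays. Intensities were not used here, so neither brightness nor signal over background is known.

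Probes were named from the array platform's public annotation, whose symbols can be old: 5064 probes had 1 gene symbol, 9 had several and were left unnamed, and 687 were not listed. The gene IDs of 5043 probes were found in a current rat gene table of assembly GRCr8, and 0 symbols needed an update. This gave 4390 genes. No genome was used, so no positions are printed.

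Each array's median over all its probes was subtracted, probes of 1 gene were averaged per array, and unnamed probes stood as themselves. Centred and averaged values were rounded at the level of floating-point residue, so that a ratio of exactly 0 has no sign and equal values have no spread. Of 5086 features, the 3819 measured on all 3 arrays (3395 named genes and 424 unnamed probes) were tested with limma 3.58.1 in R 4.3.3, with an intercept-only lmFit, eBayes and Benjamini-Hochberg adjustment, two-sided, at an adjusted p of 0.05. The design fixed before the data were examined assumed a known log base. Because the base was not stated, the ratios were used as deposited, which leaves the test statistics unaffected, and folds are given for base 10 and base 2. The count of features with the same sign and at least 1.5-fold on every array needs a base, and both are given. Gene lists were tested with camera at an inter-gene correlation of 0.01 over the 28 of 30 fixed lists with at least 4 measured genes. Camera at an estimated correlation and fry were run beside it. With an estimated correlation camera tests on the 2 residual degrees of freedom of the 3 arrays. With a fixed one its degrees of freedom follow the number of genes, so those p-values take little account of the few arrays. Correlations between arrays were computed across genes.

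Genes were named by a rule fixed before the data were examined. It takes the 12 highest and 12 lowest genes past the threshold with 1 sign on all arrays, filled up where fewer passed with genes of 1 sign ordered by their smallest absolute ratio. It adds up to 4 genes with the smallest p-values per list, and 21 genes of water, sodium, osmolyte and growth control wherever they were measured. Slc6a12, Nfat5 and Atp6v1b1 of these were not measured here. For lists that did not pass, the text gives some or all of these genes, chosen after the values were seen. Rps6kb1, Gapdh and Hprt1 were named outside the rule, also after the values were seen.

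The fit was tested on simulated data of the same 3819 features with 200 changed ones. It recovered 14.9%, 89.6% and 100% of features shifted by 0.15, 0.30 and 0.50, with 10 false calls. The noise was independent and normal, with variances from limma's own fitted prior, and held no array, probe or dye effects. These shares therefore check the fit and do not give its recovery on the real arrays. Alternatives set beforehand were no centring, scaling to the same spread, genes measured on at least 2 arrays, single probes, array weights, each array left out, a robust prior, no prior, another threshold, a test against a minimum fold, exact zeros left out, other folds, subsets of genes, and other list tests. Block-wise centring, centring on genes measured on all 3 arrays, base 2 and the ribosomal list without its kinase gene were chosen after seeing the data. Tables were joined and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.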

Results

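RNA of the kidney inner medulla, the zone where collecting ducts concentrate the urine, was compared between rats given lithium for 1 month and control rats. Lithium causes nephrogenic diabetes insipidus, in which the collecting duct responds poorly to vasopressin, and the study asked which medullary transcripts differ in this condition. Each of 3 arrays carried RNA of lithium-treated rats in the red channel and RNA of control rats in the green channel. Arrays 1 and 2 held pools of 2 rats per channel and array 3 held 1 rat per channel, so all 3 arrays formed 1 group of direct comparisons. The deposited value of a probe was a log ratio whose base was not stated, and a fold is therefore given for base 10 and for base 2. Ratios above 0 were read as higher in lithium-treated medulla, which is likely because the labels name lithium RNA as channel 1, but the table did not state the direction. Of 5760 probes, 5582, 5682 and 4287 had a value on arrays 1, 2 and 3, and 3819 genes or unnamed probes were measured on all 3 arrays. No spot intensities were used here, so the number of arrays limits the precision.

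Lithium-treated inner medulla had higher transcript levels of a secreted injury marker, a steroid-inactivating enzyme and several epithelial and metabolic genes. Every array had lithium RNA in red, so dye effects and treatment cannot be told apart for any gene, higher or lower. Lcn2, the iron-siderophore-binding lipocalin released by injured tubules, rose by a mean log ratio of 0.53 ± 0.15 (SD, n = 3), which is 3.39-fold in base 10 or 1.44-fold in base 2. Hsd11b2, the enzyme that inactivates glucocorticoids in aldosterone target cells, rose by 0.49 ± 0.10, which is 3.07-fold in base 10 or 1.40-fold in base 2. Krt19, a keratin of simple epithelia, rose by 0.44 ± 0.15, and Prom1, a glycoprotein of membrane protrusions, by 0.39 ± 0.02. The mitochondrial creatine kinase Ckmt1 rose by 0.37 ± 0.12 and the lysosomal protease cathepsin D (Ctsd) by 0.34 ± 0.06. Enzymes of glutamine, retinaldehyde and alanine metabolism rose as well, with 0.32 ± 0.07 for Gls2, 0.30 ± 0.04 for Aldh1a1 and 0.27 ± 0.02 for Gpt. The limma adjusted p-values of these 9 genes lay between 0.0234, shared by Lcn2, Hsd11b2 and Prom1, and 0.0476, shared by Ckmt1 and Gpt. Not past the threshold, the heparan sulfate enzyme Ndst1 had a ratio of 0.26 ± 0.02 (adjusted p = 0.0560), the glutamate receptor Grik2 one of 0.28 ± 0.08 (adjusted p = 0.0726) and the matricellular gene Ccn3 one of 0.37 ± 0.17 (adjusted p = 0.0853).

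A secretoglobin, 2 protease inhibitor genes, a collagen gene and an annexin gene had the lowest ratios among transcripts that fell in lithium-treated medulla. Scgb2a1, a secretoglobin, fell by 0.60 ± 0.25 (SD, n = 3), a ratio of 0.249 in base 10 or 0.658 in base 2. Serpina3l, of the serine protease inhibitor family, fell by 0.59 ± 0.16, and Spink1l, a Kazal-type protease inhibitor, fell by 0.51 ± 0.13. Col10a1, a collagen chain known from growth cartilage, fell by 0.51 ± 0.11, and Anxa4, a calcium-dependent phospholipid-binding annexin, fell by 0.49 ± 0.15. Dgkz, a diacylglycerol kinase, fell by 0.35 ± 0.03, the transcription factor gene Mycn fell by 0.28 ± 0.04, and the unnamed probe 7.3.10.2 fell by 0.29 ± 0.04. The limma adjusted p-values of these 8 features ran from 0.0234 to 0.0476. Arrays 1 and 2 had a long negative tail, with 3.46% and 9.73% of values more than 0.3 below the median. Only 0.251% and 0.264% lay as far above it. Among probes with a value on array 3, as these 8 have, 0.586% and 2.77% were under −0.3. The cause of the tail stayed open, so these falls may be partly technical. Both Serpina3l and Spink1l have close relatives that a probe can also bind, so their assignment is uncertain. The relative Serpina3n, looked up after the values were seen, had a mean ratio of −0.34 (adjusted p = 0.0865). Next in order and not past the threshold were the cytoskeletal gene Add2 at −0.28 ± 0.06 (adjusted p = 0.0560), the channel gene Cnga1 at −0.34 ± 0.19 (adjusted p = 0.117), the granzyme Gzmc at −0.30 ± 0.11 (adjusted p = 0.0782), and Akr1b1, aldose reductase, at −0.27 ± 0.05 (adjusted p = 0.0616). The probes of Add2 read −0.12 and −0.33 on array 2, and the second had no value on array 3. Its mean and SD therefore mix different probes across arrays.

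**Figure D1:**
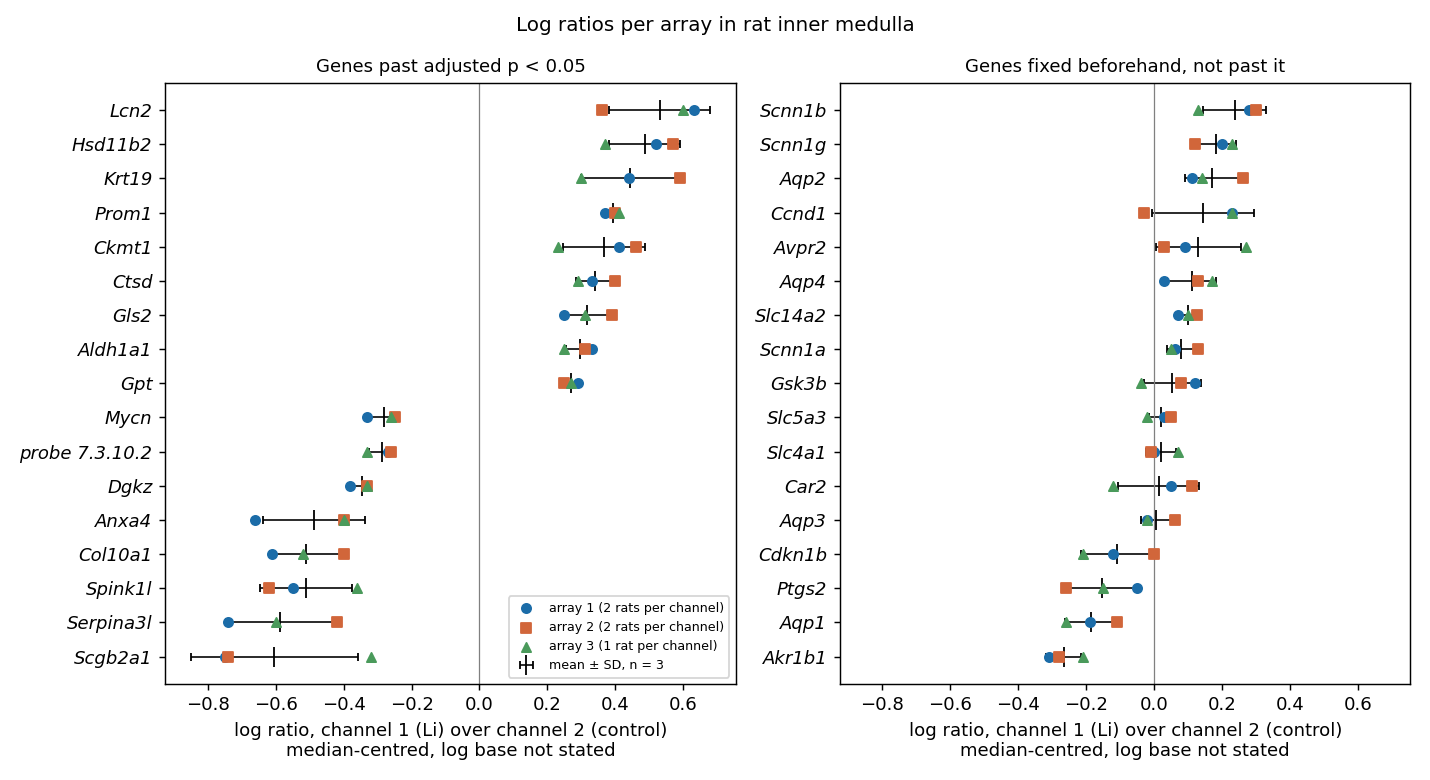
Median-centred log ratio (horizontal axis, base not stated) of the 17 features past the threshold, left, and of 17 genes fixed beforehand that did not pass it, right, with 1 symbol per array and a bar for mean ± SD (n = 3). Lcn2, at 0.63, 0.36 and 0.60, has the highest mean and Scgb2a1, at −0.75, −0.74 and −0.32, the lowest.

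Across the 3819 features, 17 passed a limma adjusted p of 0.05, 9 of them higher and 8 lower, and each had the same sign on all 3 arrays. When the arrays were scaled to the same spread, 98 features passed, 35 higher and 63 lower. At an unadjusted p of 0.05, 658 features passed, 371 of them higher. All 17 were measured by a single probe each. With any 1 array left out, limma called 0 features, while 172, 606 and 445 had an unadjusted p under 0.05 without array 1, 2 and 3. An exact sign test of 1 gene on 3 arrays cannot go below p = 0.25, so the calls rest on the variance that limma shares between genes.

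Each of the 17 also passed a count that uses no error model when the base was taken as 10. Both criteria use the same 3 ratios, so this overlap gives no separate support. In base 10, 46 features were at least 1.5-fold apart in the same direction on every array, 18 higher and 28 lower, against 2, 2 and 0 when the sign of array 3, 2 or 1 was turned. In base 2 the count was 0, and base 10 was put first only after the data were seen. The prostacyclin receptor Ptgir was in this group with ratios of −0.24, −0.88 and −0.20, although its adjusted p was 0.169. One sign on all 3 arrays was found for 1478 features (38.7%, against 25% by chance), 922 of them higher and 556 lower. The excess of higher ones came from centring on all probes, since centring on the genes measured on all 3 arrays, chosen after seeing the data, gave 717 higher and 737 lower. Counts of list members above and below 0 depend on the centring in the same way.

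Genes of sodium transport and aldosterone response in the collecting duct were shifted upward as a group. Of 16 measured genes, 12 had a ratio above 0 and 4 below, with a median of 0.09 and a camera adjusted p of 0.0353. This call was lost with an estimated correlation (adjusted p = 0.933), with directional fry (adjusted p = 0.301), and without array 1 or array 2 (adjusted p = 0.119 and 0.194). It was also lost with camera on ranks (adjusted p = 0.0510), which limits the weight of a single high gene such as Hsd11b2. Hsd11b2 rose among all genes tested and the other 15 did not pass. The epithelial sodium channel subunits Scnn1b and Scnn1g stood at 0.24 ± 0.09 (SD, n = 3, limma adjusted p = 0.105) and 0.18 ± 0.06 (adjusted p = 0.130), and Scnn1a at 0.08 ± 0.04 (adjusted p = 0.360). Hsd11b1, which regenerates active glucocorticoid, had a ratio of −0.15 ± 0.02 with an adjusted p of 0.15. Adjusted over the list alone, 6 genes were higher and 2 lower. Over 13 alternatives the adjusted p ran from 0.00334 to 0.933 and passed in 8.

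The collecting duct's water and urea transport genes, which vasopressin controls, did not pass as a group. Aqp2, the vasopressin-regulated water channel, had a ratio of 0.17 ± 0.08 (SD, n = 3, limma adjusted p = 0.153), with values of 0.11, 0.26 and 0.14 on the 3 arrays. Lithium is known to lower Aqp2 abundance in the collecting duct, so these values leave doubt about the assumed direction of all ratios. Aqp3, the basolateral water channel, stood at 0.01 ± 0.05 (adjusted p = 0.953) and Aqp4 at 0.11 ± 0.07 (adjusted p = 0.265). The vasopressin receptor gene Avpr2 stood at 0.13 ± 0.12 (adjusted p = 0.278), the urea transporter gene Slc14a2 at 0.10 ± 0.03 (adjusted p = 0.261) and Prkar2a, a regulatory subunit of protein kinase A, at −0.23 ± 0.19 (adjusted p = 0.183). Of the 22 members 13 lay above 0 and 9 below, none passed either among all genes or adjusted over the list alone, and camera gave an adjusted p of 0.631.

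Ribosomal protein genes shifted upward together, by a small amount each. Of 70 measured genes 61 lay above 0, 8 below and 1 at 0, with a median log ratio of 0.07 and a camera adjusted p of 6.94e-06. The call was lost with an estimated correlation (adjusted p = 0.856) and with directional fry (adjusted p = 0.279). The correlation was estimated at 0.0128, close to the fixed 0.01, so correlation between the genes hardly accounts for the loss in that setting. That setting tests on 2 residual degrees of freedom, which the fixed one does not, so few lists could pass there. The small p-value of the fixed setting in turn takes little account of having only 3 arrays. The list was fixed by symbol prefix and takes in Rps6kb1, a kinase gene at 0.04, without which, a setting chosen after seeing the data, the camera adjusted p was 6.04e-06. Rpl31 at 0.17 ± 0.04, Rps2 at 0.18 ± 0.07, Rps20 at 0.18 ± 0.09 and Rpl23a at 0.16 ± 0.06 (SD, n = 3) had the smallest limma p-values, with adjusted p from 0.134 to 0.153. No ribosomal gene passed on its own, either among all genes or adjusted over the list alone. The list passed in 11 of 13 alternatives. Of its probes 2.74% were empty on array 3, against 1473 of all 5760 probes. Probes empty there read lower on arrays 1 and 2. An effect of spot brightness or dye on this shift was not tested and cannot be told apart from lithium here.

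Genes of cholesterol and fatty acid synthesis shifted downward together. Of 14 genes 12 lay below 0 and 2 above, with a median of −0.09 and a camera adjusted p of 0.00405. The call was lost with an estimated correlation (adjusted p = 0.856) and with directional fry (adjusted p = 0.301). It was also lost with genes measured on at least 2 arrays (adjusted p = 0.246). The correlation was estimated at −0.0035, below the fixed one, so correlation between these genes hardly accounts for the loss in that setting. As for the ribosomal list, that setting tests on 2 residual degrees of freedom, which the fixed one does not. The malic enzyme gene Me1 stood at −0.14 ± 0.06, and the sterol pathway genes Idi1, Lss and Fdps stood at −0.13 ± 0.04, −0.18 ± 0.13 and −0.17 ± 0.14 (SD, n = 3), with limma adjusted p from 0.176 to 0.215. None of the 14 passed, also when adjusted over the list alone. The list passed in 10 of 13 alternatives.

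Cytoskeletal and keratin genes shifted upward, 17 of 21 lying above 0, 3 below and 1 at 0, with a median of 0.08 and a camera adjusted p of 0.0310. The list's adjusted p was 0.933 with an estimated correlation, 0.0594 without array 1 and 0.474 without array 2, where its median was 0.05. Krt19 rose, alone of the 21 both among all genes and adjusted over the list alone. The annexin genes Anxa6 and Anxa1 stood at 0.15 ± 0.02 (SD, n = 3, limma adjusted p = 0.149) and 0.12 ± 0.02 (adjusted p = 0.185), whereas Anxa3 stood at −0.13 ± 0.02 (adjusted p = 0.176). Over 13 alternatives the list's adjusted p ran from 0.0017 to 0.933 and passed in 7. As with the ribosomal genes, few of its probes (2.86%) were empty on array 3, and an effect of spot brightness or dye was not tested.

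**Figure D2:**
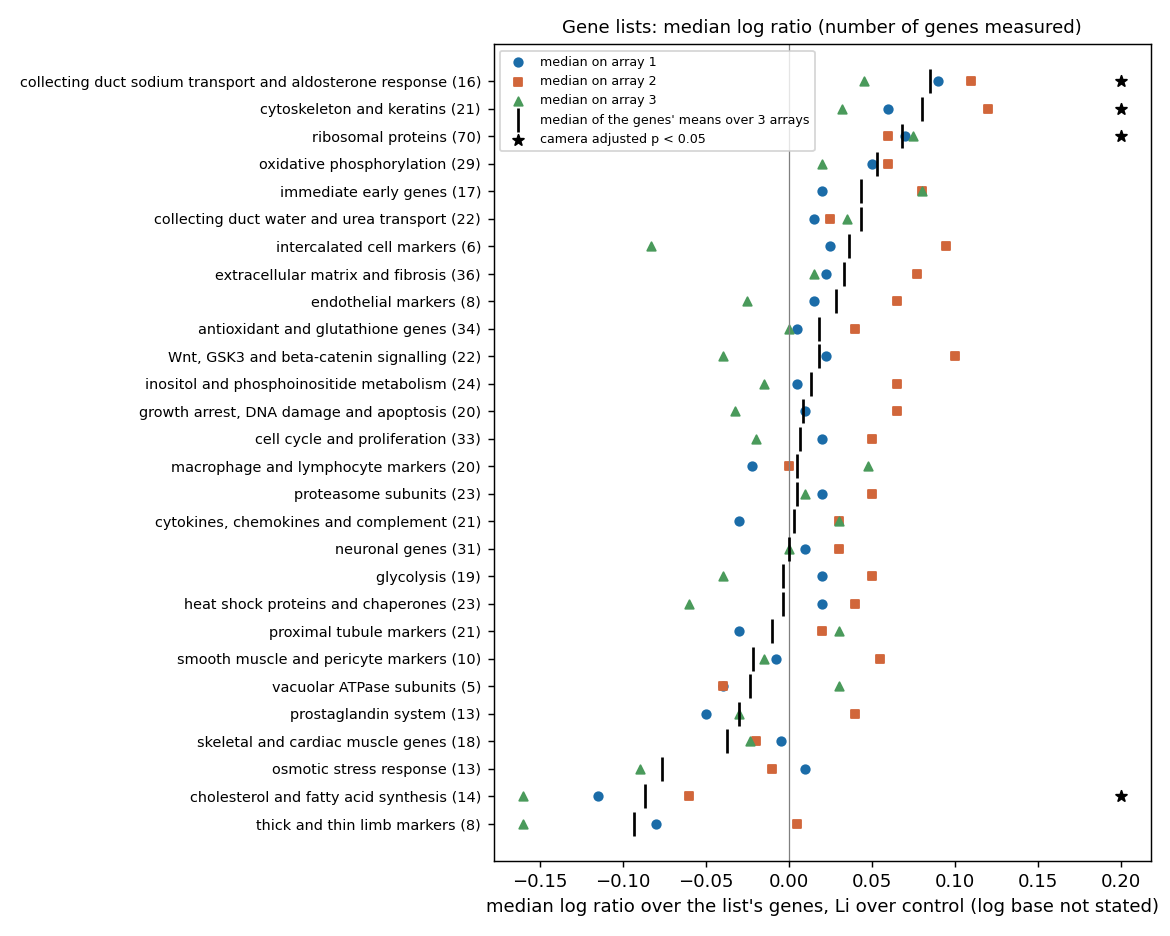
Median log ratio (horizontal axis, base not stated) of each of the 28 gene lists on each array (symbols) and of the genes' means over the 3 arrays (vertical bar), with the number of genes in parentheses and a star for a camera adjusted p under 0.05. Sodium transport, cytoskeletal and ribosomal genes lie at the top, with medians of 0.09, 0.08 and 0.07, and cholesterol genes carry the star at −0.09.

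Markers of the thick and thin limbs and genes of the osmotic stress response had medians below 0, nearer to 0 without array 3, and did not pass as lists. Among 8 limb markers 6 were below 0, with a median of −0.09 (camera adjusted p = 0.0536) that was −0.0525 without array 3. Aqp1, the water channel of the thin descending limb, stood at −0.19 ± 0.08 (SD, n = 3, limma adjusted p = 0.136) and was the only one of them past the threshold adjusted over the list alone. The uromodulin gene Umod stood at −0.18 ± 0.19 (adjusted p = 0.256) and Bst1 at −0.11 ± 0.05 (adjusted p = 0.239). Of 13 osmotic stress genes 7 lay below 0, with a median of −0.08 (camera adjusted p = 0.155) that was −0.035 without array 3. Akr1b1 and S100a4 were lower adjusted over the list alone, the latter at −0.24 ± 0.12 (adjusted p = 0.126). The myo-inositol transporter gene Slc5a3 stood at 0.02 ± 0.04 (adjusted p = 0.831). Over 13 alternatives the limb list's adjusted p ran from 0.0362, with the arrays scaled to the same spread, to 0.933, and it passed in 4.

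Lists of energy metabolism and protein turnover did not pass. Of 29 oxidative phosphorylation genes 24 lay above 0, with a median of 0.05 (camera adjusted p = 0.0700), led by Cox8a at 0.12 ± 0.02 and Atp5mc3 at 0.11 ± 0.02 (SD, n = 3). This list passed in 4 of 13 alternatives, with an adjusted p from 0.0200, under block-wise centring chosen after seeing the data, to 0.933. The 19 glycolysis genes had a median of −0.00333 (adjusted p = 0.706), which was 0.04 without array 3. Among them, the glucose transporter gene Slc2a3 stood at −0.17 ± 0.07 and Aldoa at 0.15 ± 0.05. The 23 proteasome subunit genes had a camera adjusted p of 0.705, with Psmb9 at 0.18 ± 0.03 and Psmb5 at 0.13 ± 0.06. The 23 heat shock and chaperone genes also had an adjusted p of 0.705, and Hspb6, a small heat shock protein gene at −0.24 ± 0.05 (limma adjusted p = 0.0797), passed adjusted over the list alone. Among 34 antioxidant and glutathione genes (camera adjusted p = 0.955), the glutathione transferase genes Gsta1 and Gsta3 stood at 0.14 ± 0.05 and 0.12 ± 0.04.

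Lists of signalling and growth control, among them the enzymes that lithium is known to inhibit, did not pass as groups. Among 24 genes of inositol and phosphoinositide metabolism (camera adjusted p = 0.937), Impa1, the inositol monophosphatase that lithium inhibits, stood at −0.21 ± 0.06 (SD, n = 3, limma adjusted p = 0.105) and was lower adjusted over the list alone. The second probe of Impa1 disagreed in size, at −0.01 and −0.03 on arrays 1 and 2 where the first read −0.39 and −0.52. The first had no value on array 3, so the value of −0.16 there came from the second probe alone. The mean, SD and call of Impa1 therefore mix different probes across arrays. Gsk3b, the kinase that lithium inhibits, stood at 0.05 ± 0.08 (adjusted p = 0.585). Its list of 22 genes of Wnt, GSK3 and beta-catenin signalling had a camera adjusted p of 0.940, with Wnt4 at −0.16 ± 0.08 and Ctnnb1 at 0.13 ± 0.07. Of 33 cell cycle genes (adjusted p = 0.955), Cdk2 stood at 0.19 ± 0.06, Cdk1 at −0.21 ± 0.12, Ccnd1 at 0.14 ± 0.15 (limma adjusted p = 0.278) and Cdkn1b at −0.11 ± 0.11 (adjusted p = 0.316). The 20 growth arrest and apoptosis genes had an adjusted p of 0.955, with Bad at 0.17 ± 0.03 and Gadd45g at −0.13 ± 0.05. The probes of Bad read 0.10 and 0.27 on array 1, and the first had no value on array 3, so its SD mixes probes too. Of 17 immediate early genes 12 lay above 0 (adjusted p = 0.628), and Egr1, at 0.30 ± 0.17 (limma adjusted p = 0.117), was higher adjusted over the list alone. Among 13 prostaglandin genes (adjusted p = 0.667), Ptgs2, the inducible cyclooxygenase, stood at −0.15 ± 0.11 (limma adjusted p = 0.194) and Pla2g4a at −0.13 ± 0.06.

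Inflammation and matrix genes, and markers of other cell types, did not pass as lists either. Among 21 cytokine, chemokine and complement genes (camera adjusted p = 0.992), Lcn2 rose, and the chemokine Cxcl12, at −0.17 ± 0.06 (SD, n = 3), was lower adjusted over the list alone. The 20 macrophage and lymphocyte markers had an adjusted p of 0.940, with Cd4 at 0.16 ± 0.03 and the integrin Itgam at −0.39 ± 0.29. Among 36 matrix and fibrosis genes (adjusted p = 0.843), Timp3 stood at −0.20 ± 0.08 and Col5a1 at −0.22 ± 0.11. The 8 endothelial markers had an adjusted p of 0.705, with Tie1 at 0.11 ± 0.06, and the 10 smooth muscle and pericyte markers one of 0.703, with Pdgfra at −0.14 ± 0.19. Proximal tubule markers, which stand for carried-over outer zones, numbered 21 (adjusted p = 0.955), and Slc22a6, an organic anion transporter gene at 0.20 ± 0.04, was higher adjusted over the list alone. The 6 intercalated cell markers, with Atp12a at −0.14 ± 0.05, Slc4a1 at 0.02 ± 0.04 and Car2 at 0.01 ± 0.12, and the 5 vacuolar ATPase subunits, with Atp6ap1 at 0.15 ± 0.11, both had an adjusted p of 0.955. The probes of Slc4a1 disagreed in sign, at 0.12 and −0.12 on array 1, and the latter had no value on array 3. Median and mean differed in sign for the ATPase subunits (−0.02 and 0.02) and the proximal tubule markers (−0.01 and 0.01), and for the cytokine list both lay above 0 while camera pointed downward.

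Genes of tissues other than kidney served as a background. The 31 neuronal genes had a median of 0.00 and a camera adjusted p of 0.873, and Grik2 was higher adjusted over the list alone. The 18 skeletal and cardiac muscle genes had a median of −0.04, which was 0.005 without array 3, and an adjusted p of 0.398, and the myosin gene Myh2, at 0.24 ± 0.12 (SD, n = 3), was higher adjusted over the list alone. Of the probes for these lists, 31.7% and 37.5% had no value on array 3. The muscle list passed as lower with genes measured on at least 2 arrays (adjusted p = 0.0278), which was the lowest of 13 alternatives and the only one past the threshold, the highest being 0.933. Red blood cell markers, with Hba-a1 at 0.15 ± 0.06, and urothelial markers, with Krt20 at −0.06 and Sprr1a at 0.05 ± 0.15 beside Krt19, had 2 and 3 measured genes and were not tested as lists.

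The arrays repeated each other unevenly. Across the 3819 features, which are not independent replicates, array 1 correlated with array 2 at Pearson r = 0.465 (Spearman rho = 0.363) and with array 3 at r = 0.481 (rho = 0.464). Arrays 2 and 3 correlated at r = 0.157 (rho = 0.125). Among genes spotted 10 times or more, the SD between spots of 1 array ran from 0.0372 for Gapdh on array 1 to 0.109 for Hprt1 on array 2.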

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

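Block-wise centring, centring on genes measured on all 3 arrays, base 2 and the ribosomal list without its kinase gene were chosen after seeing the data. The count of 17 features became 98 with arrays scaled to the same spread, 40 with genes measured on at least 2 arrays (4 higher, 36 lower, 8 shared), 11 with single probes, 1055 with array weights (4.52, 0.371 and 0.596 for arrays 1 to 3), 94 with a robust prior (35 higher, 59 lower), 49 at an adjusted p of 0.1, and 6 or 0 in limma's test against 1.2-fold in base 10 or base 2, where 180 and 12 had an unadjusted p under 0.05. Without the variance prior it was 0, with 442 at an unadjusted p under 0.05, and 9 features with equal values on all arrays could not be tested. Leaving out any 1 array gave 0, with fewer arrays to estimate the variance. The cause was not tested for the other settings. It stayed at 18, 21, 20 and 15 without centring, without exact zeros, with block-wise centring (16 shared) and with centring on complete genes (14 shared). The 46 features of the 1.5-fold count became 244 and 9 at a lower and a 2-fold limit, 0 in base 2, and 68 to 104 with 1 array left out. The 4 lists past the threshold became 2 to 5 with 1 array left out. With an estimated correlation, tested on 2 residual degrees of freedom, 0 passed (1 at an unadjusted p of 0.05). Directional fry gave 0 (2 unadjusted) and mixed fry, which tests change in either direction, gave 17. Under the other settings 4 or 5 passed. Correlations of arrays 1 and 2, 1 and 3, and 2 and 3 were 0.573, 0.549 and 0.222 over features at least 1.5-fold on 1 array in base 10, and 0.621, 0.656 and 0.335 in base 2. With block-wise centring they were 0.551, 0.465 and 0.248. By rank, with the centring as reported, the first was 0.363. Ratios of 8 named genes near 0 changed sign, none past the threshold: Aqp3 to −0.0133 without centring, −0.0146 with array weights, −0.01 centred on complete genes and −0.02 to 0.02 with 1 array left out; Car2 to −0.00667, −0.015 block-wise, −0.00333 on complete genes and −0.035 to 0.08 with 1 array left out; Pdgfra to 0.0048 with array weights; Atp6v0e1 to 0.0133 with single probes; and with 1 array left out Aqp6 ran from −0.035 to 0.165, Actg2 from −0.01 to 0.08, Sprr1a from −0.025 to 0.125 and Slc4a1 from −0.005 to 0.035. Signal over background is unknown, so what it limits is unknown too.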

Other observations

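Of the tests below, those on probes empty on array 3, on the tail per block, on the position of the features past the threshold, on single probes and on Hsd11b2 and Krt19 were chosen only after the results were seen. The test on genes of other tissues was set before its value was seen, but was prompted by such genes standing among the lowest ratios. No biological explanation was tested for the first pattern.

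Further genes outside the fixed lists were at least 1.5-fold apart in base 10 on every array, and they are named here after their values were seen. The epithelial adhesion gene Epcam had ratios of 0.23, 0.19 and 0.20, and Nrp1, a neuropilin, 0.21, 0.19 and 0.37. On the lower side, the lipid-regulating receptor gene Pparg had −0.29, −0.43 and −0.20, the calcium-sensing receptor gene Casr −0.23, −0.18 and −0.36, and the kinase gene Camk2a −0.19, −0.31 and −0.25. Their limma adjusted p-values ran from 0.0782 to 0.0918, so none passed. Aqp2 stood above 0 on every array, although lithium is known to lower its abundance in the collecting duct. If the deposited ratios were control over lithium, every direction in the text would turn.

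Ratios on arrays 1 and 2 had a long negative tail, with 3.46% and 9.73% of values more than 0.3 below the median against 0.251% and 0.264% above it. The tail was spread over the slide, which argues against a region of blocks as the whole cause. Of 32 blocks, 25 on array 1 and 31 on array 2 had more than 0.5 times the array's share of values under −0.3. Centring each block on its own median left 3.22% and 9.68% under −0.3, but block medians lay within 0.07 of 0, so this correction could not have removed the tail. Probes empty on array 3 differed from the others by −0.22 in median on array 2 and by −0.09 on array 1, and 30.7% of them were under −0.3 on array 2 against 2.77% of the others. Neuronal and muscle genes, 67 in number, lay below the others by a difference of −0.0375 in the mean of arrays 1 and 2, and by −0.01 among the 49 with a value on array 3. Such genes prompted this test and many of their probes are among those empty on array 3, so it gives no separate support. A candidate explanation is that dim spots read low, which would make low ratios of poorly expressed genes partly technical, but intensities were not used here to test it.

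The 17 features past the threshold were weighed against position, single-probe effects and the signs of whole arrays. Block position explained 22% of the variance of ratios on array 3, 6.81% on array 1 and 2.71% on array 2. After block-wise centring 16 of the 17 passed, but block medians lay within 0.12 of 0, so this correction could hardly remove them. The smallest mean among the 17 was 0.27, for Gpt, which argues against shifts of whole blocks as the whole cause. Position within a block was not tested. Between arrays, the same probe correlated more than different probes of 1 accession, by a mean of 0.226 (95% bootstrap interval 0.10 to 0.354, 154 genes). Mean r was 0.305 for the same probe and 0.0792 for different probes of 1 accession, and 0.328 and −0.0228 for probes of different accessions (164 genes), so most of what repeats may belong to the probe and its dye response rather than to the transcript. None of the 17 has a second probe, so this explanation and lithium cannot be told apart for them. Turning the sign of 1 whole array gave at most 0 features against 17, with 89, 114 and 23 at an unadjusted p of 0.05 in limma for arrays 3, 2 and 1, but 4 sign patterns are too few for a share under 0.05.

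Hsd11b2 and the epithelial keratin gene Krt19 rose while principal cell genes of the collecting duct such as Aqp2 and Aqp3 had smaller ratios. A larger share of collecting duct cells in the lithium RNA would raise the transcripts of these cells alike. The other 35 genes of both collecting duct lists, without Aqp2 and Aqp3, ran from −0.23 for Prkar2a to 0.24 for Scnn1b, with a median of 0.05 and an SD of 0.10 among genes. Hsd11b2 exceeded their median by 0.44 ± 0.10 (SD, n = 3) and Krt19 by 0.40 ± 0.13, and both lay above Scnn1b on every array, by at least 0.24 and 0.16. The 35 include widely expressed genes that a share would raise less. The 6 principal cell genes Aqp2, Aqp3, Aqp4, Avpr2, Scnn1a and Slc14a2 also had a median below Hsd11b2, by 0.38 ± 0.11 and by 0.25 on array 3. This set takes in Aqp2 and Aqp3, from which the pattern was drawn, and leaves out Scnn1b and Scnn1g, which stood higher at 0.24 and 0.18. These principal cell genes thus did not stand as high as Hsd11b2. But Hsd11b2 and Krt19 were picked for their high ratios, so their lead over other genes was partly fixed by that choice. Lithium is also known to lower Aqp2. These gaps therefore cannot decide on such a share, which stays open, alone or beside regulation per cell. The sodium transport list lay above 0 and the limb markers below it, at medians of 0.09 and −0.09 (camera adjusted p = 0.0353 and 0.0536), so a shift between tubule segments stays open for these lists and was not tested. Position of the block is argued against, since block medians lay within 0.12 of 0 on every array and the lower of the Hsd11b2 and Krt19 means was 0.47 after block-wise centring. A share of urothelium, which also makes Krt19, was not tested. Its markers Krt20, at −0.06, and Sprr1a, at 0.05 ± 0.15, stood far below Krt19 at 0.44, but 2 genes of unknown signal leave it open, and dye effects of single probes stay open too.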
